A study of Homo sapiens with 12 samples.

How the data were processed

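Total RNA from 12 samples of the H1 line, 3 per group in 4 groups (day 6 and day 15, high and low seeding density), was extracted with TRIzol and made into mRNA libraries, per the labels' protocols. The submitters' processing notes name Bowtie2, RSEM, the GRCh38 genome and DESeq2 1.4.5, without saying which step each served. The authors deposited a single table with expected counts per gene and library, which hold fractions, as RSEM gives them. Per the file headers, the same table holds the authors' log2 fold changes and their q-values for 4 comparisons, whose sign for the density comparison at day 15 was turned so that low density is set against high density throughout. The table has 18583 data lines, of which 94 were emptied for this work and are not analysed here, and 20 are pieces of broken annotation cells. The remaining 18469 gene rows, all mRNA and with no repeated symbol, were used. No column of per-sample values was left unmatched to a sample. Coordinates are those of the deposited table (GRCh38). Of 17219 genes with a chromosome in both the table and a RefSeq gene table, 9641 had the same chromosome and start, so gene models differ between the builds of the annotation. The strand column of the deposited table was not used.

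Totals ran from 15653523 to 20576416 counts per library, and 14941 to 15573 genes per library had at least 10 counts. The deposited expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups as the design (15963 genes), scaled by TMM, and fitted with the quasi-likelihood model (robust option off) with 1 mean per group over all 12 libraries and 8 residual degrees of freedom. Contrasts were low minus high density at day 6 and at day 15, the difference between those, and day 15 minus day 6 at each density. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes at adjusted p below 0.05 were counted as higher or lower. Standard errors are the absolute log2 fold change over the square root of F. CPM values are on TMM-scaled library sizes. Overlaps between days were tested with Fisher's exact test. Python 3.11.15 with pandas 2.3.3 read the table and drew the figures.

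Before the data were examined, 37 gene lists with 596 genes were fixed, of which 566 had a row and 552 were tested. Of the lists, 35 had at least 5 tested members; 1 had fewer and 1 had none. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists of a contrast, and again with the correlation estimated from the residuals. Members were also adjusted over the list alone. Terms deposited with the genes (hallmark, KEGG and gene ontology sets of 10 to 500 tested genes) were tested with a one-sided hypergeometric test against the tested genes with at least 1 term of that kind, for each direction of each density comparison.

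Genes were named by a rule fixed before the data were examined. For each density comparison it takes the 10 higher and 10 lower genes with the largest change among called genes with at least 5 CPM in the higher group and all 3 libraries of one density above all 3 of the other. It takes 5 and 5 for the other comparisons (for the difference between days without the condition on libraries), up to 4 list members with the largest change and at least 1 CPM in the higher group, and the 2 most abundant members where none passed. It also takes 17 blood, stem cell and vessel genes whatever their values. After the values were seen, list examples that lost their call when 1 library was left out were passed over in the text. At day 6, 43 of the 126 named values lost their call that way, at day 15 10 of 165, and for the difference between days 26 of 142. Among the members passed over are all that the rule named in the day 6 endothelial, glycolysis, tricarboxylic acid cycle and oxidative phosphorylation lists. The same holds for the p53 response list and the serine and one-carbon list of day 6.

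The pipeline was tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed. The changed genes were drawn from those above 2 CPM at high density and went up and down in nearly equal numbers. For the day 6 comparison (15839 genes) it called 46.3% of genes changed by an absolute log2 of 0.5, 92.5% at 1 and all at 2, and 2.45% of calls were of unchanged genes. For the day 15 comparison (15844 genes) the shares were 53.7%, 94.0% and all, with 5.71% false. These rates do not cover scaling where many more genes change or where globins take a larger share of counts, as in the real libraries. Replicate similarity was measured by Pearson correlation of log2 CPM with 1 added, and by a chi-square over genes with a summed count of at least 20 between replicates of a group, which gave 3.43 to 36.1 per degree of freedom, so no library was present a second time.

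Alternatives chosen before the data were examined were DESeq2 size factors, library totals alone, no filter, a filter of 1 CPM in 6 libraries, the DESeq2 1.42.0 Wald test, limma-voom, adjusted p below 0.01, an absolute log2 fold change of at least 1, the replicate number as a block, the globins left out, each library left out in turn, only the 6 libraries of a comparison, and fry in place of camera. List members with each library left out, and granule genes at day 15 under library totals alone, were added after the data were examined. Genes whose reads may be shared with close relatives or overlapping genes include HBA1 and HBA2, HBG1 and HBG2, HBB and HBD, GYPA and GYPB, DEFA3, and RSC1A1.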

Results

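RNA was sequenced from the human embryonic stem cell line H1 during a stepwise induction of embryoid bodies, which are floating aggregates of differentiating stem cells, toward red blood cells. Wells of 6-well plates were seeded with 600000 cells (high density, the control) or 200000 cells (low density). Cells were collected on day 6, after stages with BMP4, Activin A and CHIR99021 and then with VEGF165 and bFGF, and on day 15, after a stage with erythropoietin, SCF, TPO and IL-3. The design was 4 groups of 3 libraries, 12 in all, so every mean below is of n = 3. The labels do not say that the 3 replicates of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of gene lists set the members against all other genes and, at the preset correlation of 0.01, treat genes as nearly independent. List p-values therefore depend strongly on the number of genes and are no measure of the spread between samples or cultures. The labels also do not say whether embryoid bodies and cells suspended around them were collected together.

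Library totals were 15653523 to 19781937 counts at day 6 high density and 19883756 to 20576416 at day 6 low density. They were 18560485 to 19108099 at day 15 high density and 16218914 to 19205370 at day 15 low density. Replicates of a group correlated at 0.985 to 0.997 over log2 counts. The first principal component held 81.5% of the variance and separated the days, and the second held 12.5% and separated the densities at day 15. Globin transcripts made up 0.0665 ± 0.0108% of counts at day 6 high density and 0.145 ± 0.0112% at day 6 low density. At day 15 they made up 1.35 ± 0.0902% at high density and 8.02 ± 1.11% at low density. Day 15 low density replicate 3 lay nearest to the high density libraries of its day, with 6.74% globin against 8.52% and 8.79% in replicates 1 and 2. Of 18469 gene rows used, 15963 passed the expression filter and were tested. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera with the same adjustment. Abundances are CPM, mean ± standard deviation, and counting intervals and floors given for rare transcripts cover counting error only.

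**Figure D1:**
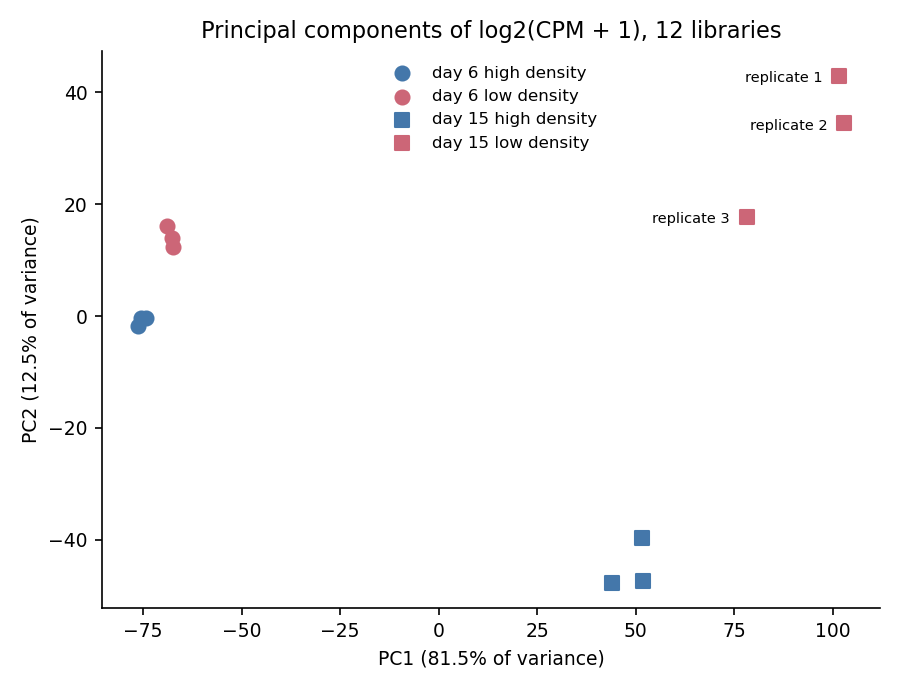
Principal components of the 12 libraries. The first component (81.5%) separates day 6 from day 15, and the second (12.5%) separates high from low density at day 15, with low density replicate 3 nearest to the high density libraries.

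At day 6, embryoid bodies from low density wells carried more transcripts of growth-factor and stress-induced immediate early genes than those from high density wells. They also carried more globin, erythroid membrane and platelet-lineage transcripts. FOS, a transcription factor induced within minutes of stimulation, rose from 259.2 ± 62.9 to 909.5 ± 15.8 CPM, and embryonic globin HBE1 rose from 208.1 ± 35.6 to 463 ± 39.0 CPM (n = 3 each). The pluripotency factor POU5F1 fell from 27.1 ± 1.05 to 9.35 ± 1.28 CPM. In total 958 genes were higher and 738 lower at low density, with a median absolute log2 fold change of 0.637 among the 1696, and 135 and 254 of them changed at least 2-fold. Each gene named by size of change in this and the next comparison had all 3 libraries of one density above all 3 of the other.

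Of 12 immediate early genes, which encode transcription factors and phosphatases switched on by signalling without new protein synthesis, 11 were higher and 1 was not past the threshold (11 higher adjusted over the list alone). The list median was log2 1.4 (adjusted p = 5.96e-43), and this list kept its call with an estimated correlation (0.000609). FOSB rose by log2 1.96 (adjusted p = 7.3e-05; 61.4 ± 20.1 to 239.9 ± 24.8 CPM) and JUN by 1.89 (adjusted p = 3.22e-06; 46.7 ± 6.56 to 173.5 ± 18.1 CPM). FOS (gene ID 2353, chr14:75278828-75282230) rose by 1.81 (standard error 0.142; adjusted p = 7.95e-06) and EGR1 by 1.68 (adjusted p = 6.43e-06; 153.6 ± 25.6 to 493.3 ± 14.6 CPM). ZFP36 rose by 1.65 (adjusted p = 4.7e-05), the phosphatase gene DUSP1 by 1.56 (adjusted p = 4.14e-06) and JUNB by 1.5 (adjusted p = 3.22e-06). SERPINE1, a secreted protease inhibitor induced by TGF-beta, rose by 1.5 (adjusted p = 0.00103; 6.59 to 18.6 CPM). Among the hallmark sets, TNFA signalling via NFKB, which includes many immediate early genes, held 51 of the higher genes out of 185 tested (18.8 expected, adjusted p = 5.75e-09).

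**Figure D2:**
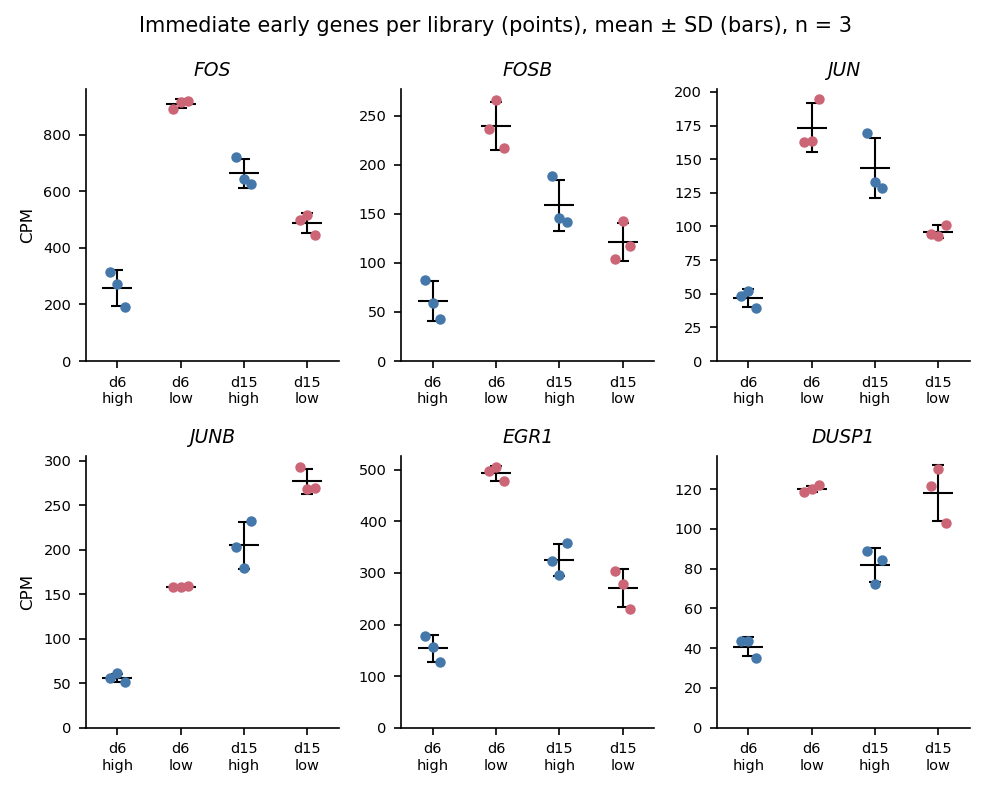
Immediate early genes in each library. At day 6 low density, 11 of 12 were higher than at high density (FOS 259.2 to 909.5 CPM), while at day 15 the list median was log2 -0.23.

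Of 10 globins, which carry oxygen, 9 were higher and 1 was not past (9 adjusted over the list alone), with median 1.33 (adjusted p = 2.78e-23, 0.0347 with an estimated correlation). HBA2 rose by 1.65 (adjusted p = 4.37e-05; 18.7 ± 3.6 to 58.4 ± 2.44 CPM), HBZ by 1.49 (0.000106), HBE1 by 1.15 (0.000507) and HBG1 by 1.11 (0.000321), and HBG2 rose by 1.12 and HBA1 by 1.38. The counts of HBA1 and HBA2, and of HBG1 and HBG2, may share reads because their sequences are nearly identical. HBB, the adult globin, rose by 1.91 from 0.321 to 1.23 CPM (0.00468), or by 2.53 without day 6 high density replicate 2. Of 22 erythroid membrane and blood group genes, 13 were higher, 1 lower and 8 not past (13 and 1 over the list alone), median 0.65 (adjusted p = 5.92e-13, 0.0454 with an estimated correlation). Among them the water channel AQP1 rose by 1.25, GYPB by 1.18, RHAG by 1.10 and GYPA by 0.98 (14.3 to 28.0 CPM), whereas the anion exchanger SLC4A1 was not past (0.32, adjusted p = 0.495). Of 14 erythroid transcription factors, 9 were higher and 5 not past (10 higher over the list alone), median 0.75 (adjusted p = 5.02e-11, adjusted p = 0.0745 with an estimated correlation). GATA1 (gene ID 2623, chrX:48775644-48801346) rose by 1.11 from 20.9 ± 3.49 to 44.8 ± 0.573 CPM, GFI1B rose by 1.05, KLF1 by 0.98 and IKZF1 by 0.95. Of 14 megakaryocyte and platelet genes, 11 were higher and 3 not past (14 higher over the list alone), median 1.05 (adjusted p = 1.46e-19, 0.0454 with an estimated correlation). Examples were PF4 (1.22), TUBB1 (1.17), PLEK (1.14) and GP1BB (1.09), which encode platelet granule, cytoskeletal and receptor proteins.

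Of 15 blood progenitor genes, 7 were higher and 8 not past (7 higher and 1 lower over the list alone), median 0.62 (adjusted p = 8.01e-06, adjusted p = 0.0942 with an estimated correlation). SPI1 rose by 1.14, GFI1 by 0.90, ANGPT1 by 0.79 and RUNX1 by 0.74 (57.5 to 95.7 CPM), while CD34 was not past (0.23, adjusted p = 0.147). Of 18 monocyte, macrophage and granulocyte genes, 6 were higher and 12 not past (7 higher over the list alone), median 0.62, or 0.33 with rare transcripts at their counting bound (adjusted p = 0.00111, adjusted p = 0.371 with an estimated correlation). CSF1R rose by 1.12, FCER1G by 1.04 and CD33 by 0.92. Of 15 heme synthesis genes, 4 were higher and 11 not past (6 over the list alone), median 0.12 (adjusted p = 0.00369, adjusted p = 0.377 with an estimated correlation). ALAS2, the first enzyme of erythroid heme synthesis, rose by 1.24 from 8.83 to 20.8 CPM (0.00059), and it was the only member still called when day 6 high density replicate 1 was left out. Of 17 iron uptake and EPO signalling genes, 4 were higher, 1 lower and 12 not past (5 and 1 over the list alone), median 0.19 (adjusted p = 0.0155, adjusted p = 0.371 with an estimated correlation). TFR2, an iron sensor of erythroblasts, rose by 0.84. The transferrin receptor TFRC was just above the threshold (0.30, adjusted p = 0.0547), and it passed with DESeq2 (0.024), limma-voom (0.0425) and the replicate block (0.0403). Of 17 late erythroid maturation genes, 3 were higher and 14 not past (3 over the list alone), median 0.11 (adjusted p = 0.0237, adjusted p = 0.403 with an estimated correlation); BLVRB rose by 0.59. Of 20 endothelial genes, 4 were higher and 16 not past (4 over the list alone), median 0.25 (adjusted p = 0.00227, adjusted p = 0.479 with an estimated correlation), and the VEGF receptor KDR was not past (0.23, adjusted p = 0.433). With library totals alone, 0 endothelial, 2 heme synthesis and 2 iron uptake and EPO signalling genes were higher. Of 11 mast cell, basophil and eosinophil genes, none passed and the median (-0.03) and test differed in sign (adjusted p = 0.939); PRG2 (-0.03) and CLC (-1.0) were the most abundant.

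Pluripotency genes and some neural genes were lower at day 6 low density. Of 13 pluripotency genes, 4 were lower and 9 not past (5 lower over the list alone), median -0.28 (adjusted p = 8.92e-07, 0.0454 with an estimated correlation). SOX2 fell by log2 4.6 (2.94 to 0.114 CPM), POU5F1 by 1.54 (adjusted p = 4.64e-05), L1TD1 by 1.44 and ZFP42 by 0.71. Of 11 neural and ectoderm genes, 5 were lower and 6 not past (1 higher and 5 lower over the list alone), median -1.19 (adjusted p = 0.00121, adjusted p = 0.146 with an estimated correlation). ZIC2 fell by 3.10 and TFAP2B by 1.64, and only 2 members were lower in some fits that left out 1 library. The largest decreases in genes above 5 CPM included the epithelial surface gene TACSTD2 (-2.45, adjusted p = 2.04e-05; 5.79 ± 0.861 to 1.05 ± 0.186 CPM) and the retinoic acid binding gene CRABP1 (-2.34, 0.000114). AMER2 (-2.09, 9.62e-05), FOXI3 (-2.02, 6.24e-05), SBK2 (-1.94, 0.000114), RAB17 (-1.93, 0.00373), LRRC3B (-1.75, 0.000169) and TMPRSS4 (-1.70, 0.000136) followed. P2RY11 (-2.07, adjusted p = 0.0166) lost its call without day 6 low density replicate 1 (0.0838) and without high density replicate 2 (-1.22, 0.0696), and was at -2.67 without low density replicate 3, and the epithelial factor GRHL2 (-1.64, 0.0149) without low density replicate 3 (0.078) and with DESeq2 (0.106). KEGG tight junction genes were over-represented among the lower genes (20 of 148, 6.15 expected, adjusted p = 0.00289).

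Of 16 mesenchyme and smooth muscle genes, 9 were higher and 7 not past (12 over the list alone), median 0.52 (adjusted p = 2.31e-08, adjusted p = 0.0942 with an estimated correlation). DCN rose by 1.19, DES by 1.07 and COL1A1 by 0.87 (1906 to 3482 CPM), which encode matrix and muscle filament proteins; leaving out 1 library gave 5 to 7 higher and library totals alone 6. Of 12 basement membrane and matrix genes, 2 were higher and 10 not past (2 over the list alone), median 0.39 (adjusted p = 0.0238, adjusted p = 0.593 with an estimated correlation). SPARC was at 0.69 and COL18A1 at 0.50. Without day 6 high density replicate 1 that list was at 0.0803. Of 17 endoderm and liver genes, 3 were higher and 14 not past (3 over the list alone), median 0.45 (adjusted p = 0.0148, adjusted p = 0.377 with an estimated correlation), and under library totals alone 0 were higher. Of 14 primitive streak and mesoderm genes, 1 was higher, 1 lower (TBX6, -0.73) and 12 not past (2 and 1 over the list alone; median -0.13, adjusted p = 0.697). Of 12 cardiac muscle genes, 2 were higher, 1 lower and 9 not past (2 and 1 over the list alone; adjusted p = 0.78). MYL4 was at 1.04 and MYH6 at -0.93. The median of that list was close to no change and differed in sign from its test.

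Of 45 oxidative phosphorylation genes, 4 were higher and 41 not past (0 over the list alone), median 0.22 (adjusted p = 1.67e-06, adjusted p = 0.43 with an estimated correlation). Of 18 tricarboxylic acid cycle genes, 3 were higher and 15 not past (9 over the list alone), median 0.21 (adjusted p = 0.0011, adjusted p = 0.43 with an estimated correlation). No gene of either list was higher under library totals alone (0 for each). Of 22 glycolysis genes, 3 were higher, 1 lower and 18 not past (5 and 1 over the list alone), median 0.12 (adjusted p = 0.0465, adjusted p = 0.439 with an estimated correlation), and without day 6 low density replicate 1 the list was at 0.0954. Of 15 fatty acid oxidation genes, 1 was higher (SLC25A20, 0.61) and 14 not past (1 over the list alone), median 0.20 (adjusted p = 0.0158, adjusted p = 0.371 with an estimated correlation), and without day 6 low density replicate 3 the list was at 0.0827. Of 20 hypoxia response genes, 5 were higher, 2 lower and 13 not past (6 and 3 over the list alone; median 0.09, adjusted p = 0.132), including LOX (1.07), ADM (0.82) and DDIT4 (0.73); without day 6 high density replicate 3 the list was at 0.0377. Scaling by library totals alone left 3 hypoxia response genes higher and 3 lower, and 1 glycolysis gene higher and 1 lower. The broader hallmark hypoxia set was over-represented among the higher genes (39 of 185, 18.8 expected, adjusted p = 0.000456). None of 8 pentose phosphate genes (median 0.12, adjusted p = 0.243; TKT 0.08, PGD 0.13) and none of 21 cholesterol synthesis genes (median 0.04, adjusted p = 0.439; HMGCS1 -0.09, DHCR24 0.03) passed, over all genes or over the list alone. Of 11 serine and one-carbon genes 1 was higher and 10 not past (1 over the list alone; median 0.07, adjusted p = 0.792). None of 18 S phase genes (median 0.04, adjusted p = 0.609; MCM7 0.03, MCM4 -0.01) and none of 17 G2 and M phase genes (median 0.00, adjusted p = 0.792; TOP2A -0.12, MKI67 -0.05) passed, over all genes or over the list alone, and the G2 and M phase median and test differed in sign. The signs of the cholesterol, serine, S phase and G2 and M phase medians, and of the YAP and TAZ median, changed under another scaling.

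Of 14 p53 response genes, 3 were higher and 11 not past (6 over the list alone), median 0.16 (adjusted p = 0.0151, adjusted p = 0.184 with an estimated correlation), and under library totals alone 1 was higher. All 3 lost their call in a fit that left out 1 library (adjusted p = 0.0645, 0.181 and 0.135). The hallmark p53 pathway set held 32 higher genes of 190 (19.4 expected, adjusted p = 0.0491) and the IL6, JAK and STAT3 signalling set 18 of 76 (7.74 expected, adjusted p = 0.0142). Of 11 WNT target genes, 2 were lower and 9 not past (1 higher and 4 lower over the list alone), median -0.40 (adjusted p = 0.00882, adjusted p = 0.273 with an estimated correlation). The receptor LGR5 was at -1.04. Of 13 YAP and TAZ target genes, 2 were higher, 1 lower and 10 not past (2 and 1 over the list alone; median 0.08, adjusted p = 0.609). CCN2 was at 0.94. Of 12 BMP and TGF-beta target genes, 2 were higher, 1 lower and 9 not past (3 and 2 over the list alone; median 0.22, adjusted p = 0.213). SERPINE1 was at 1.5 and ID2 at -0.35. Of 11 NOTCH pathway genes, 1 was lower (DLL1, -1.10) and 10 not past (1 over the list alone; median 0.10, adjusted p = 0.697). Of 14 endoplasmic reticulum and amino acid stress genes, 1 was higher (ATF3, 0.78), 1 lower and 12 not past (2 and 2 over the list alone; median 0.12, adjusted p = 0.282). The hallmark epithelial mesenchymal transition set held 48 higher genes of 192 (19.6 expected, adjusted p = 4.6e-07), KEGG platelet activation 35 of 121 (9.41 expected, adjusted p = 4.81e-09) and hallmark heme metabolism 40 of 191 (19.5 expected, adjusted p = 0.000421). The authors' deposited table called 1820 genes higher and 1514 lower at q below 0.05 for this comparison, and held 1624 of the 1696 genes called here (95.8%), all in the same direction. The number of calls depended on the libraries in the fit: with the 6 day 6 libraries alone it was 2159 higher and 2040 lower, and without day 6 low density replicate 1 it was 405 higher and 333 lower. With library totals alone the balance turned, at 560 higher and 1001 lower.

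At day 15, cells from low density wells carried far more transcripts of hemoglobin, heme synthesis and red cell membrane genes than cells from high density wells. SLC4A1, the main anion exchanger of the red cell membrane, rose from 169.4 ± 30.1 to 1440 ± 140.1 CPM, and HBE1 rose from 4303 ± 443.9 to 30750 ± 6035 CPM (n = 3 each). ITGB6, an epithelial integrin, fell from 65.8 ± 25.6 to 1.58 ± 1.91 CPM, and of the low density libraries replicate 3 held most of it (3.77 CPM, against 0.248 and 0.720). In total 4359 genes were higher and 4383 lower, with a median absolute log2 fold change of 0.619 among the 8742, and 662 and 1743 of them changed at least 2-fold.

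Of 10 globins, 9 were higher and 1 was not past (9 over the list alone), median 2.82 (adjusted p = 5.25e-19, 0.0259 with an estimated correlation). HBE1 (gene ID 3046, chr11:5268345-5269945) rose by 2.84 (adjusted p = 1.47e-08), HBZ by 3.07 (7.61e-09; 2407 ± 197.2 to 20210 ± 5071 CPM), HBA2 by 3.05 (3.85e-09) and HBG2 by 2.46 (5.11e-08). HBA1 rose by 2.81, HBG1 by 2.56 and the minor alpha-like globin HBM by 3.40, while adult HBB rose by 3.75 but reached only 5.88 CPM. Of 22 erythroid membrane and blood group genes, 21 were higher and 1 lower (21 and 1 over the list alone), median 2.37 (adjusted p = 4.35e-52, 0.0016 with an estimated correlation). SLC4A1 (gene ID 6521, chr17:44248390-44268161) rose by 3.09 (standard error 0.13; adjusted p = 1.2e-09), the spectrin genes SPTA1 and SPTB by 3.05 and 3.01 and GYPA by 2.89, and AQP1 was the 1 that was lower. Of 15 heme synthesis genes, 14 were higher and 1 not past (14 over the list alone), median 1.70 (adjusted p = 1.17e-28, 0.0116 with an estimated correlation), including ALAS2 (2.80; 192.6 to 1341 CPM), HMBS (2.60; 91.1 to 550.9 CPM), FECH (2.25) and the mitochondrial carrier SLC25A39 (2.12). Of 17 iron uptake and EPO signalling genes, 14 were higher, 1 lower and 2 not past (14 and 1 over the list alone), median 0.91 (adjusted p = 1.59e-15, 0.0126 with an estimated correlation). SLC25A37, which imports iron into mitochondria, rose by 2.46, TFR2 by 2.41, the ferrireductase STEAP3 by 2.39 and TFRC by 1.81. Of 17 late erythroid maturation genes, 14 were higher and 3 not past (14 over the list alone), median 1.33 (adjusted p = 1.97e-15, 0.0126 with an estimated correlation), among them HEMGN (3.05) and the globin chaperone AHSP (2.94). Of 14 erythroid transcription factors, 11 were higher, 2 lower and 1 not past (11 and 2 over the list alone), median 1.12 (adjusted p = 7.18e-08, adjusted p = 0.151 with an estimated correlation). KLF1 rose by 2.65 (44.1 to 277 ± 29.7 CPM), TAL1 by 1.60, GFI1B by 1.49 and GATA1 by 1.4, while BCL11A fell by 1.60. Genes with the largest increases included further red cell genes, such as the carbonic anhydrase CA1 (3.58, adjusted p = 8.72e-10; 26.9 ± 4.22 to 322.4 ± 43.2 CPM), CTSE (3.28, 1.29e-08) and NT5DC4 (3.56, 3.87e-09).

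**Figure D3:**
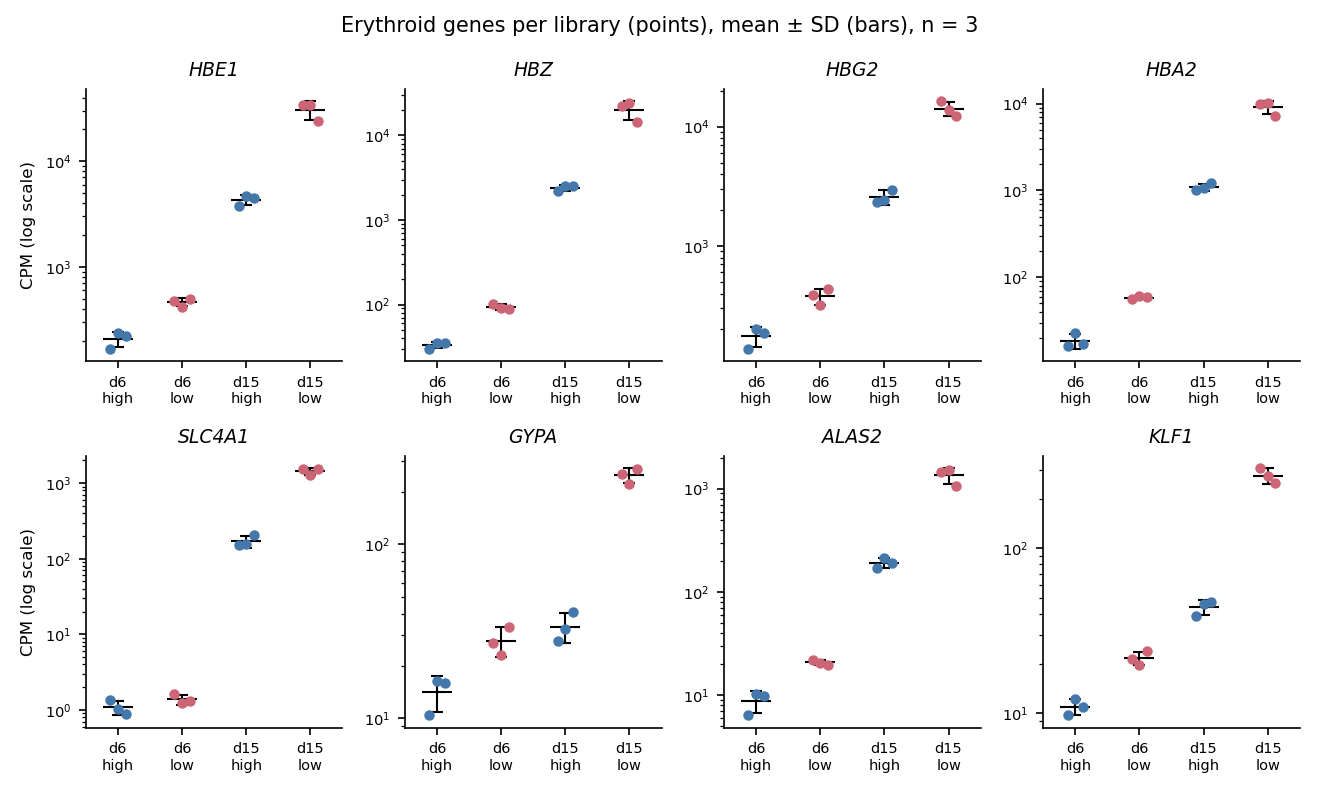
Erythroid genes in each library. SLC4A1 rose from 169.4 to 1440 CPM and HBE1 from 4303 to 30750 CPM between day 15 high and low density.

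Other genes with large increases were CAMKV (3.90, adjusted p = 3.79e-10; 2.88 to 43.2 ± 2.93 CPM), HEPACAM2 (3.23, 2.03e-07) and RSC1A1 (6.31, 4.38e-07; 0.272 to 22.3 CPM), whose locus overlaps DDI2 (0.55), so the counts of the pair may share reads. Without day 15 high density replicate 1, RSC1A1 was at 7.66. Of 17 endoderm and liver genes, 13 were higher, 1 lower and 3 not past (13 and 1 over the list alone), median 1.79 (adjusted p = 3.29e-05, adjusted p = 0.184 with an estimated correlation). TTR rose by 3.28, AFP by 3.25 (2.44 ± 1.19 to 23.2 ± 10.4 CPM), APOA2 by 3.14 and FGG by 2.49, all plasma proteins made by yolk sac endoderm and fetal liver, and AHSG rose by 5.92 to 9.75 ± 7.26 CPM. AHSG was at 5.09 without day 15 low density replicate 1 and at 6.83 without high density replicate 3. Of 18 S phase genes, 17 were higher and 1 not past (18 over the list alone), median 0.87 (adjusted p = 1.87e-08, adjusted p = 0.219 with an estimated correlation). CDT1 was at 1.30, CDC45 at 1.04 and MCM2 at 0.98. All 17 G2 and M phase genes were higher (17 over the list alone), median 0.76 (adjusted p = 1.77e-07, adjusted p = 0.248 with an estimated correlation). NUSAP1 was at 1.14, CENPE at 1.12 and CCNA2 at 1.01. Hallmark E2F targets held 145 higher genes of 197 (69 expected, adjusted p = 8.96e-27) and KEGG ribosome 104 of 132 (40.4 expected, adjusted p = 1.36e-27). Of 14 p53 response genes, 11 were higher and 3 not past (11 over the list alone), median 0.61 (adjusted p = 4.5e-06, 0.0225 with an estimated correlation), including GDF15 (2.28), which erythroblasts secrete, FDXR (1.17) and the apoptosis genes BBC3 (0.87) and BAX (0.86). Under library totals alone 8 of the p53 response genes were higher and 2 lower, with median 0.38.

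Among other blood lists, 14 of 18 monocyte, macrophage and granulocyte genes were higher and 4 not past (14 over the list alone), median 0.52 (adjusted p = 0.00627, adjusted p = 0.462 with an estimated correlation). CD14 rose by 1.56, C1QB by 1.46 and S100A8 by 1.07 (186.1 to 391 CPM), and without day 15 high density replicate 1, or without low density replicate 1, 8 members were higher. Library totals alone gave 6 higher and 1 lower, with median 0.28. Of 11 mast cell, basophil and eosinophil genes, 6 were higher, 1 lower and 4 not past (6 and 1 over the list alone; median 0.46, adjusted p = 0.28). The histamine enzyme HDC was at 0.58, and under library totals alone 0 were higher. Of 14 megakaryocyte and platelet genes, 4 were higher and 10 not past (2 over the list alone; median 0.17, adjusted p = 0.245). TUBB1 was at 0.97 and GP1BB at 0.48. Under library totals alone 1 member was higher and the median changed sign (-0.06). Of 15 blood progenitor genes, 8 were higher, 3 lower and 4 not past (8 and 3 over the list alone; median 0.40, adjusted p = 0.38), including PROM1 (1.30), SPN (0.89), RUNX1 (0.56), CD34 (-0.46; 106.9 to 77.8 CPM) and HOXA9 (-1.18). Of 20 endothelial genes, 1 was higher, 8 lower and 11 not past (1 and 8 over the list alone; median -0.26, adjusted p = 0.267). NOS3 was at -1.73, SOX7 at -1.08 and VWF at -0.83. Under library totals alone 1 endothelial gene was higher and 12 lower, and 6 blood progenitor genes were higher and 5 lower. Without day 15 low density replicate 3, 13 endothelial genes were lower (list adjusted p = 0.0341) and KDR, not past with it (-0.32, adjusted p = 0.135), was at -0.68.

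Of 11 neural and ectoderm genes, 8 were lower and 3 not past (8 over the list alone), median -2.63 (adjusted p = 0.00398, adjusted p = 0.196 with an estimated correlation), including TFAP2B (-4.56), TFAP2A (-3.96; 164.4 to 10.6 CPM) and MAP2 (-1.62). Of 13 YAP and TAZ target genes, which respond to cell contact and tension, 12 were lower and 1 not past (12 over the list alone), median -1.04 (adjusted p = 5.74e-06, adjusted p = 0.248 with an estimated correlation). AMOTL2 fell by 3.24 (145.7 to 15.5 CPM), CCN1 by 2.92 and AJUBA by 2.25, and KEGG Hippo signalling held 78 lower genes of 150 (38.3 expected, adjusted p = 9.27e-10). Of 12 BMP and TGF-beta target genes, 1 was higher, 9 lower and 2 not past (1 and 9 over the list alone), median -0.77 (adjusted p = 0.00138, adjusted p = 0.242 with an estimated correlation), including TGFBI (-2.75; 1794 to 266.6 CPM), ID4 (-1.76) and ID1 (-1.35). Of 11 WNT target genes, 1 was higher, 6 lower and 4 not past (1 and 6 over the list alone), median -0.99 (adjusted p = 0.0177, adjusted p = 0.248 with an estimated correlation), including the feedback inhibitors RNF43 (-3.01), AXIN2 (-1.62) and NKD1 (-1.47). Of 12 basement membrane and matrix genes, 1 was higher, 5 lower and 6 not past (1 and 5 over the list alone; median -0.41, adjusted p = 0.13). LAMA1 was at -3.44, LAMB1 at -1.90 and NID2 at -1.27; without day 15 low density replicate 3, 11 were lower (adjusted p = 1.22e-06). The largest decreases among genes above 5 CPM were in MUC4 (-5.42, adjusted p = 7.7e-08), ITGB6 (chr2:160099671-160271888; -5.40, 3.15e-07), MUC16 (-5.32, 4.08e-08), CBLC (-5.26, 1.75e-07) and PAPPA2 (-5.14, 6.36e-06; 215.7 ± 77.1 to 6.17 ± 8.59 CPM). ANKRD63 (-4.93, 2.48e-07), NOS2 (-4.88, 3.11e-08), KRT17 (-4.83, 2.23e-07), KCNK12 (-4.79, 1.22e-06) and MTUS2 (-4.72, 1e-07) followed. The sizes and order of these decreases rest on day 15 low density replicate 3. Without it PAPPA2 was at -7.50, ITGB6 at -7.11, MUC16 at -6.67, CBLC at -6.45, KCNK12 at -6.42, ANKRD63 at -6.12, MUC4 at -6.06, NOS2 at -5.81 and MTUS2 at -5.51. KEGG axon guidance held 96 lower genes of 175 (44.7 expected, adjusted p = 6.43e-14) and hallmark epithelial mesenchymal transition 95 of 192 (49.4 expected, adjusted p = 2.14e-10).

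Of 14 primitive streak and mesoderm genes, 3 were higher, 5 lower and 6 not past (3 and 6 over the list alone; median -0.59, adjusted p = 0.256). HAND1 was at -2.29, ISL1 at -1.77 and TBX6 at -1.56. Of 16 mesenchyme and smooth muscle genes, 3 were higher, 5 lower and 8 not past (3 and 5 over the list alone; median -0.10, adjusted p = 0.843). DES was at 1.84, TWIST1 at -1.36 and THY1 at -1.29. Of 12 cardiac muscle genes, 1 was higher, 4 lower and 7 not past (1 and 4 over the list alone; median -0.51, adjusted p = 0.28). MYL4 was at 2.52, ACTC1 at -3.11 and RYR2 at -1.51. Of 13 pluripotency genes, 3 were higher, 4 lower and 6 not past (3 and 4 over the list alone; median -0.12, adjusted p = 0.359). L1TD1 was at -2.89 and LIN28A at -2.39, and POU5F1 was not past (-0.12, adjusted p = 0.626). Of 11 NOTCH pathway genes, 1 was higher (HES1, 0.95), 4 lower and 6 not past (1 and 4 over the list alone; median -0.17, adjusted p = 0.166). HEY1 was at -1.68 and DLL1 at -1.59. Of 12 immediate early genes, 2 were higher (DUSP1, 0.53; JUNB, 0.43), 4 lower (including JUN, -0.58) and 6 not past (2 and 4 over the list alone; adjusted p = 0.839). Of 14 endoplasmic reticulum and amino acid stress genes, 3 were higher, 4 lower and 7 not past (3 and 4 over the list alone; median -0.09, adjusted p = 0.636). DDIT3 was at 0.88 and ATF3 at -1.11. When scaled by library totals alone, the lists of this paragraph leaned further to lower: 1 higher and 7 lower for primitive streak, 2 and 8 for mesenchyme, 1 and 6 for cardiac muscle, 1 and 5 for pluripotency, 1 and 9 for NOTCH, 1 and 7 for immediate early and 1 and 8 for stress genes.

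Of 45 oxidative phosphorylation genes, 36 were higher and 9 not past (37 over the list alone), median 0.43 (adjusted p = 1.22e-05, adjusted p = 0.564 with an estimated correlation). COX7C was at 0.89, COX7B at 0.71 and UQCRB at 0.67, subunits of the respiratory chain. Under library totals alone 19 of them were higher and the median was 0.20. Of 18 tricarboxylic acid cycle genes, 10 were higher, 2 lower and 6 not past (10 and 2 over the list alone; median 0.26, adjusted p = 0.166). IDH3G was at 0.64, SDHB at 0.50 and SUCLG2 at -0.51. Under library totals alone 2 were higher and 4 lower, with median 0.03. Of 22 glycolysis genes, 8 were higher, 5 lower and 9 not past (8 and 5 over the list alone; median -0.05 with the test pointing up, adjusted p = 0.903). Under library totals alone 3 were higher and 12 lower. The red cell pyruvate kinase gene PKLR rose by 3.05 (36.3 to 301.2 CPM), while the glucose transporters SLC2A3 (-2.03; 2371 ± 323.1 to 582.5 ± 96.1 CPM) and SLC2A1 (-1.36; 2333 ± 261.6 to 909.9 ± 106.9 CPM) and the hexokinase HK2 (-0.67) fell. Of 20 hypoxia response genes, 4 were higher, 7 lower and 9 not past (4 and 7 over the list alone; median -0.15, adjusted p = 0.526). The oxygen sensor EGLN1 was at -1.27, NDRG1 at -0.96 and P4HA1 at -0.93. Under library totals alone 1 was higher and 12 lower. In the main scaling the hallmark hypoxia set held 70 lower genes of 185 (47.6 expected, adjusted p = 0.00465). Of 8 pentose phosphate genes, 3 were higher, 1 lower and 4 not past (4 and 1 over the list alone; median 0.20, adjusted p = 0.551). TALDO1 was at 0.80, TKT at 0.47 and H6PD at -0.62. Of 15 fatty acid oxidation genes, 6 were higher, 1 lower and 8 not past (6 and 1 over the list alone; median 0.21, adjusted p = 0.166). SLC25A20 was at 0.84 and ETFB at 0.66. Of 21 cholesterol synthesis genes, 5 were higher, 6 lower and 10 not past (5 and 6 over the list alone; median -0.03, adjusted p = 0.903). INSIG1 was at 0.56, HMGCR at -0.78 and SC5D at -0.72. Of 11 serine and one-carbon genes, 4 were higher, 4 lower and 3 not past (4 and 4 over the list alone; median 0.06, adjusted p = 0.512). DHFR was at 1.14, ALDH1L2 at -1.01 and PHGDH at -0.99. The medians of the pentose phosphate, fatty acid oxidation, cholesterol and serine lists changed sign under another scaling. With library totals alone, 1 and 3, 2 and 2, 3 and 11, and 3 and 5 of their members in turn were higher and lower.

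The authors' deposited table called 3262 genes higher and 3500 lower at q below 0.05 for this comparison. Of the 8742 genes called here it held 6704 (76.7%), all in the same direction, and its log2 fold changes correlated with these at 0.998. Without day 15 low density replicate 3 the counts were 4535 higher and 5111 lower, and under library totals alone 2140 were higher and 6501 lower, so the balance of higher and lower genes rests on the scaling.

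**Figure D4:**
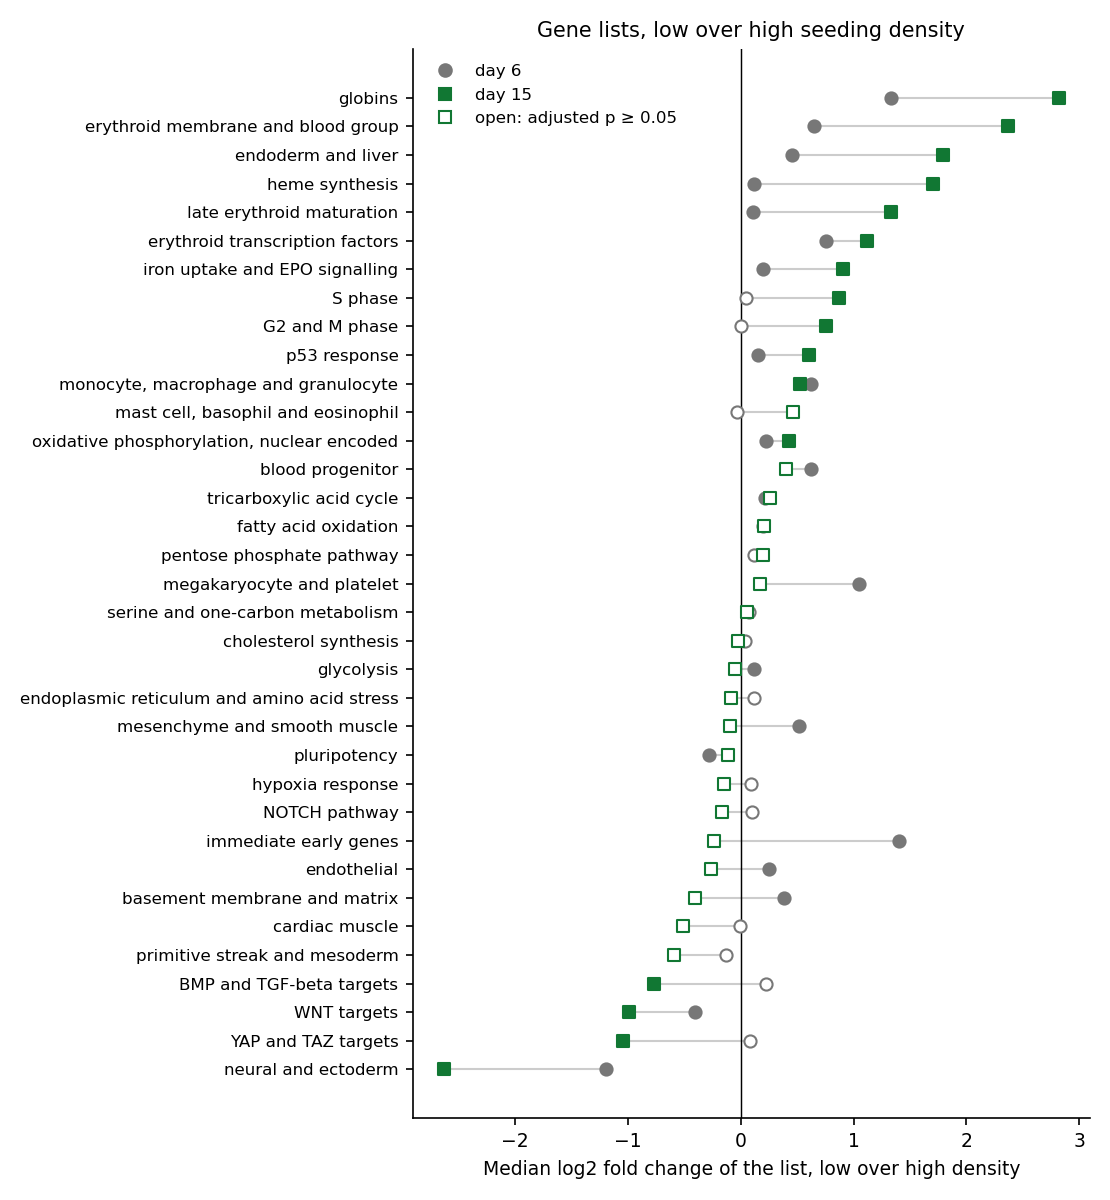
Median log2 fold change of each gene list, low against high density, at day 6 and day 15. Erythroid membrane genes were at 0.65 and 2.37, S phase genes at 0.04 and 0.87, YAP and TAZ targets at 0.08 and -1.04, and immediate early genes at 1.4 and -0.23.

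The response to density differed between the days for 5493 genes: for 2167 the change from high to low density was more positive at day 15 than at day 6, and for 3326 it was more negative. Red cell genes responded more at day 15, and immediate early genes rose as a list at day 6 and not at day 15. SLC4A1, for example, went from 1.09 to 1.38 CPM at day 6 but from 169.4 ± 30.1 to 1440 ± 140.1 CPM at day 15 (n = 3), a difference in log2 change of 2.77. JUN (chr1:58780791-58784396) went the other way, with a difference of -2.47.

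Of 22 erythroid membrane and blood group genes, 19 were more positive and 1 more negative (median difference 1.81, adjusted p = 2.46e-23, 0.0142 with an estimated correlation). SPTB was at 2.52. Of 15 heme synthesis genes 14 were more positive (1.4, adjusted p = 7.1e-27, 0.0142 with an estimated correlation). HMBS was at 2.47, and of 17 iron uptake and EPO signalling genes 13 were more positive (0.80, adjusted p = 1.42e-12, 0.0216 with an estimated correlation). SLC25A37 was at 2.29. Of 10 globins 8 were more positive and 1 more negative (1.44, adjusted p = 1.01e-05, adjusted p = 0.251 with an estimated correlation). HBE1 was at 1.68. Of 17 late erythroid genes 9 were more positive (1.42, adjusted p = 5.06e-08, adjusted p = 0.0626 with an estimated correlation). SELENBP1 was at 2.07. Erythroid transcription factors were split 5 to 2 (0.37, adjusted p = 0.00741, adjusted p = 0.45 with an estimated correlation). KLF1 was at 1.68. Of 18 S phase genes 16 (0.81, adjusted p = 1.39e-09, adjusted p = 0.222 with an estimated correlation; CDT1 1.22) and of 17 G2 and M phase genes 16 (0.79, adjusted p = 1.39e-09, adjusted p = 0.225 with an estimated correlation; NUSAP1 1.28) were more positive. The p53 response list was split 7 to 1 (0.56, adjusted p = 0.000444, adjusted p = 0.0626 with an estimated correlation; GDF15 1.69) and endoderm and liver genes 7 to 2 (1.04, adjusted p = 0.014, adjusted p = 0.404 with an estimated correlation). Of 45 oxidative phosphorylation genes 7 were more positive (0.23, adjusted p = 0.0094, adjusted p = 0.645 with an estimated correlation), and 0 over the list alone.

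Of 12 immediate early genes 10 were more negative (-1.05, adjusted p = 3.97e-11, 0.0216 with an estimated correlation). JUN was at -2.47, FOSB at -2.35, FOS at -2.26 and EGR1 at -1.95. Of 13 YAP and TAZ targets 12 were more negative (-1.10, adjusted p = 1.32e-07, adjusted p = 0.225 with an estimated correlation). CCN1 was at -3.99 and AMOTL2 at -2.75. BMP and TGF-beta targets were split 1 to 9 (-1.07, adjusted p = 3.7e-05, adjusted p = 0.173 with an estimated correlation; TGFBI -3.21) and mesenchyme and smooth muscle genes 1 to 10 (-0.68, adjusted p = 0.00576, adjusted p = 0.404 with an estimated correlation; THY1 -1.52). Of 14 megakaryocyte and platelet genes 9 were more negative (-0.86, adjusted p = 0.00436, adjusted p = 0.455 with an estimated correlation). PLEK was at -1.05 and PF4 at -0.97. Of 20 endothelial genes 9 (-0.53, adjusted p = 0.00891, adjusted p = 0.59 with an estimated correlation) and of 12 basement membrane genes 6 (-0.83, adjusted p = 0.00506, adjusted p = 0.563 with an estimated correlation; LAMA1 -3.08) were more negative. Neural and ectoderm genes were split 1 to 3 (-1.27, adjusted p = 0.0444, adjusted p = 0.4 with an estimated correlation). The largest single differences included CAMKV (4.13, adjusted p = 7.14e-07), the muscle gene SLN (-4.62, 6.43e-06; 26.9 ± 11.6 to 4.75 CPM at day 15), MUC4 (-4.6, 0.000121) and NOS2 (-4.36, 5.28e-06). ITGB6 (-4.27, 0.0278) lost its call without day 6 low density replicate 2 (0.0918). Without day 15 low density replicate 3, ITGB6 was at -5.98, NOS2 at -5.27 and MUC4 at -5.24. RSC1A1 (10.89, adjusted p = 0.00206), HEPACAM2 (4.56, 0.0273), CTSE (4.50, 0.00558) and MAGEA11 (3.88, 0.0141) rest on 3 or fewer counts in a day 6 group, and NKX2-6 (-4.52, 0.000593) on 1 count at day 15 low density, so their fitted values are no bound. Without day 6 high density replicate 3, HEPACAM2 was at 0.221 and MAGEA11 at 0.0503, and without high density replicate 1 CTSE was at 0.0687 (adjusted p).

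Genes changed by density on both days were mostly changed in the same direction. The 487 genes higher on both days exceeded the 262 expected (odds ratio 2.97, adjusted p = 8.36e-57), and the 499 lower on both exceeded 203 (odds ratio 6.1, adjusted p = 1.66e-119). Only 109 were higher at day 6 and lower at day 15 (263 expected, adjusted p = 1.75e-35), and 57 were lower then higher (202 expected, adjusted p = 2.52e-42). Fisher's test, like the tests of deposited terms, treats genes as independent, which they are not. Its p-values do not measure the spread between libraries or cultures. HBE1, GATA1, ALAS2 and GYPA were among those higher on both days, and TFAP2B was lower on both.

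Between day 6 and day 15 transcripts of globins and of myeloid granule proteins rose at both densities. HBZ rose by log2 6.17 at high density and 7.75 at low density, and SLC4A1 by 7.26 and 10.02. MPO, a granule enzyme of myeloid cells, went from 0.687 to 1706 CPM at high density and from 0.745 to 2047 CPM at low density (n = 3 each). At high density 5775 genes were higher and 5438 lower at day 15 (median absolute log2 fold change 0.811), and at low density 6017 were higher and 6287 lower (median 1). These comparisons use the same 12 libraries as those between densities, and the authors' deposited table shared 10609 (94.6%) of the calls at high density and 11214 (91.1%) at low density.

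All 18 monocyte, macrophage and granulocyte genes and all 11 mast cell, basophil and eosinophil genes were higher at day 15 at both densities. The monocyte list had medians of 5.07 (adjusted p = 8.47e-23) and 5.06 (1.27e-17), and the mast cell list 5.83 (1.34e-11) and 5.88 (2.32e-09), at high and low density in turn. For each list it was adjusted p = 0.0527 at high and 0.0371 at low density with an estimated correlation. PRTN3 rose by 11.01 and 12.02, the eosinophil peroxidase EPX by 11.41 and 12.14 and PRG2 by 10.74 and 11.32. CLC rose by 13.12 at low density (0.454 to 4109 ± 900 CPM) and PRG3 by 11.74 at high density (adjusted p = 1.2e-10; 0.101 to 372.5 CPM), or by 12.59 without day 6 high density replicate 1. With 0 counts at day 6, BPI was at least 964-fold higher at high density and at least 1550-fold higher at low density, and at high density CSTA was at least 654-fold, C1QC at least 636-fold and CD300LF at least 464-fold higher. At low density DEFA3 was at least 3860-fold and OLIG1 at least 1400-fold higher, and S100A8 was higher by a ratio of 8080 (counting interval 2760 to 39200).

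Globins were split 8 higher and 1 lower at high density (median 4.12, adjusted p = 2.09e-11) and 9 and 1 at low density (5.62, 5.45e-13), with adjusted p = 0.0575 and 0.0604 with an estimated correlation. Of 22 erythroid membrane and blood group genes, 19 were higher and 1 lower at high density (2.13, 1.4e-14, adjusted p = 0.0575 with an estimated correlation), and all 22 were higher at low density (3.47, 2.89e-33, 0.0108 with an estimated correlation). Of 15 heme synthesis genes 13 were higher and 1 lower at high density (0.88, adjusted p = 0.159 with an estimated correlation) and 15 higher at low density (2.26). ALAS2 was at 4.45 and 6.01. Of 17 iron uptake and EPO signalling genes 14 were higher at high density (0.95, adjusted p = 0.0575 with an estimated correlation) and 15 higher and 1 lower at low density (2.15). The EPO-induced PIM1 was at 4.20 and 5.10. Of 17 late erythroid genes 13 were higher and 3 lower at high density (1.0, adjusted p = 0.159 with an estimated correlation), and 14 and 2 at low density (1.86). Megakaryocyte and platelet genes were higher in 13 of 14 at high density (2.16, 6.95e-13) and in 12 at low density (1.49, 2.12e-06), with adjusted p = 0.0575 and 0.145 with an estimated correlation. PPBP was at 9.77 and 8.81. At high density no list kept its call with an estimated correlation (lowest adjusted p = 0.0527), and at low density the heme (0.0371), iron (0.0365), late erythroid (0.0392), mast cell (0.0371), monocyte (0.0371) and p53 (0.0371) lists kept it beside the membrane list.

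Of 20 endothelial genes 15 were lower at high density (-1.19) and 18 at low density (-1.81), with adjusted p = 0.295 and 0.281 with an estimated correlation. The receptor TEK was at -2.71 and -3.61 and VWF at -2.35 and -3.37. Of 14 primitive streak and mesoderm genes 11 and 12 were lower (-1.48 and -2.77; adjusted p = 0.0974 and 0.138 with an estimated correlation). Of 12 cardiac muscle genes 7 were lower at each density (-1.31 and -1.67; adjusted p = 0.0575 and 0.0604 with an estimated correlation). MYH6 was at -3.90 and -5.47. The mesoderm factor TBXT was lower by a ratio of 104 (counting interval 18.2 to 4130) at high density and 31.3 (8.4 to 263) at low density. The posterior homeobox gene CDX4 fell by 6.79 at high density (12.2 to 0.102 CPM; -7.69 without day 15 high density replicate 1) and was at least 119-fold lower at low density, where it had 0 counts at day 15. The hormone gene SST was lower by a ratio of 113 (38.3 to 550) and 465 (83.1 to 18400), and PLP1 at low density by 147 (50.2 to 717). FABP7 fell by 5.30, PTPRZ1 by 5.05 and WNT8A by 5.41 at high density, and ACTC1 by 6.23 (228.6 to 3.05 CPM) and CARTPT by 6.21 at low density. Without day 15 high density replicate 3 WNT8A was at -6.13, and without low density replicate 3 CARTPT was at -7.82.

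Of 21 cholesterol synthesis genes 17 were lower and 2 higher at high density (-1.28, adjusted p = 2.67e-09) and 18 and 2 at low density (-1.19, 4.57e-07), with adjusted p = 0.0575 and 0.0893 with an estimated correlation. HMGCR was at -1.98 and -2.77 and SQLE at -2.18 and -2.35. Of 20 hypoxia response genes 18 were higher and 2 lower at high density (1.12), and 14 and 2 at low density (0.63), with adjusted p = 0.151 and 0.337 with an estimated correlation. NDRG1 was at 3.33 and 2.16. Of 22 glycolysis genes 14 were higher and 3 lower, then 13 and 6 (adjusted p = 0.151 and 0.337 with an estimated correlation), and SLC2A1 rose by 2.22 at high density (500.6 to 2333 CPM). WNT targets were split 1 higher to 9 lower at each density (adjusted p = 0.0882 and 0.0783 with an estimated correlation), with DKK1 at -4.88 and -5.74 and LEF1 at -2.32 and -3.51. NOTCH pathway genes were split 1 to 8, then 0 to 10 (adjusted p = 0.15 and 0.141 with an estimated correlation), with DLL4 at -2.20 and -2.65. At high density 14 of 18 S phase genes were lower (-0.78, 6.43e-05, adjusted p = 0.257 with an estimated correlation), and all 17 G2 and M phase genes were (-1.02, 4.73e-07, adjusted p = 0.178 with an estimated correlation). TOP2A was at -1.95. At low density S phase genes were split 6 to 8 (-0.11, 0.717) and G2 and M phase genes 3 to 9 (-0.23, 0.223). Immediate early genes were split 11 to 1 at high density (1.09, 0.00151, adjusted p = 0.15 with an estimated correlation) and 2 to 6 at low density (-0.47, 0.499).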

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

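A test of the difference in the density effect between day 6 and day 15 picked out the results in this part; of the tests of explanations here, that of harvest stress was chosen before the result was seen and the others after it, although leaving the globins out was a setting planned beforehand for the counts of genes. For 2167 genes the effect was more positive at day 15 and for 3326 more negative. In 100 ways of regrouping the libraries 3 and 3 within each day, 2 gave at least as many genes as the real 5493: the real one, and the one with the real groups of each day and the names of 1 day exchanged (7696 genes). The highest of the remaining regroupings gave 5399, so random groupings of libraries gave as many in a share under 0.05. The regroupings also break the density effect within each day, so they do not test a difference between days against an equal effect on both.

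Of the lists, 19 had such a difference, and with an estimated correlation 15 of them lost it, all but heme synthesis, erythroid membrane and blood group, iron uptake and EPO signalling, and immediate early genes. Median differences were positive for globins (1.44), heme synthesis (1.4), erythroid transcription factors (0.37), erythroid membrane and blood group (1.81), iron uptake and EPO signalling (0.80), late erythroid maturation (1.42), endoderm and liver (1.04), oxidative phosphorylation (0.23), S phase (0.81), G2 and M phase (0.79) and p53 response (0.56). They were negative for endothelial (-0.53), megakaryocyte and platelet (-0.86), neural and ectoderm (-1.27), mesenchyme and smooth muscle (-0.68), YAP and TAZ targets (-1.10), BMP and TGF-beta targets (-1.07), basement membrane and matrix (-0.83) and immediate early genes (-1.05).

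Of 57 named genes, 46 differed between the days. Red cell genes were more positive at day 15: HBA2 1.4, HBA1 1.43, HBZ 1.58, HBG1 1.45, HBG2 1.34, HBE1 1.68, HBB 1.84, KLF1 1.68, GYPA 1.91, TFRC 1.51, SLC4A1 2.77, ALAS2 1.56 and CA1 2.72. So were RSC1A1 10.89, CAMKV 4.13, CTSE 4.50, HEPACAM2 4.56, MAGEA11 3.88, TMPRSS4 3.04, P2RY11 1.99 and POU5F1 1.42. Immediate early genes were more negative: FOSB -2.35, JUN -2.47, FOS -2.26, EGR1 -1.95, ZFP36 -1.14, DUSP1 -1.03 and JUNB -1.06, as was SERPINE1 -1.30. Other genes were more negative too: TACSTD2 -1.82, RAB17 -1.46, LRRC3B -1.80, GRHL2 -2.50, MUC4 -4.60, ITGB6 -4.27, MUC16 -4.02, CBLC -3.79, PAPPA2 -3.80, ANKRD63 -4.10, NOS2 -4.36, KRT17 -4.18, KCNK12 -3.58, MTUS2 -4.25, SLN -4.62, NKX2-6 -4.52 and CD34 -0.69. The values of RSC1A1, HEPACAM2, CTSE, MAGEA11, LRRC3B and NKX2-6 rest on 3 or fewer counts in a group and are no bound. Without 1 day 6 library the adjusted p was 0.153 for HBB (high density replicate 2), 0.0853 for CA1 (high density replicate 3), 0.221 for HEPACAM2 and 0.0503 for MAGEA11 (both high density replicate 3), 0.0687 for CTSE (high density replicate 1) and 0.0918 for ITGB6 (low density replicate 2). Only genes that the naming rule took for the difference between days were checked in this way. P2RY11, RAB17, LRRC3B, GRHL2 and PAPPA2 are among those not checked. The day 6 change of P2RY11 lost its call without high density replicate 2 (-1.22, adjusted p = 0.0696).

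The rise of erythroid genes at day 15 low density was looked at without the globins and weighed against a larger share of erythroid cells. With the globins left out of scaling and test, the erythroid membrane and blood group list had a median of 2.34 (2.37 with them). Globins took 1.35% of day 15 counts at high and 8.02% at low density, so leaving them out could move other genes only slightly. The median could hardly have fallen, so no conclusion on globin-led scaling is drawn from it. Over 20 erythroid-restricted genes with at least 5 CPM at both densities, the log2 fold changes spread by 0.599 beyond their standard errors (Cochran Q 333), from 0.29 (HBD) to 3.58 (CA1), and by 0.296 without HBD, against a larger erythroid share of unchanged cells as the only cause. Of the 20, 15 lay within 0.5 of their median of 2.85, so a larger share may still make up most of the change, with erythroid cells also at a different stage; how the parts divide was not tested. Seeding density acting on erythroid differentiation remains a hypothesis.

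The rise of immediate early genes at day 6 low density was weighed against harvest stress and a single odd library. Heat shock genes, which handling would raise as well, had a median of 0.10 (bootstrap 0.0591 to 0.216, 2 of 17 higher). That was below the cutoff chosen beforehand for stress with a heat shock response. The bootstrap resampled the 17 genes and not the libraries. Its interval therefore treats genes as independent and holds no spread between libraries. Whichever of the 6 day 6 libraries was left out, at least 10 of 12 immediate early genes were higher, against 1 library as the source. A difference in handling that raises immediate early genes alone, or with a small heat shock response, stays open, since the labels do not give collection times. A response to density may equally be at work.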

How the results depend on the processing

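Lists with a library left out and granule genes under library totals were added after the data were examined; the other alternatives were fixed before. The cause of a moved count was not tested, except that stricter thresholds call fewer genes by construction. At day 6, 958 genes were higher and 738 lower; library totals alone gave 560 higher and 1001 lower, only the 6 libraries compared 2159 and 2040, adjusted p below 0.01 373 and 296, and a log2 fold change of at least 1 135 and 254. Leaving out 1 library gave 398 (without day 6 high density replicate 1) to 632 (without high density replicate 2) higher, and 333 (without day 6 low density replicate 1) to 491 (without low density replicate 2) lower. Without high density replicate 3 there were 480 and 390, and without low density replicate 3 509 and 349. At day 15 library totals alone gave 2140 higher and 6501 lower, with the median of all genes at -0.21, and the fold minimum gave 662 and 1743. For the difference between days, library totals gave 1307 more positive and 4217 more negative (median -0.17), adjusted p below 0.01 1166 and 2134, and the fold minimum 556 and 1470. From day 6 to day 15 the fold minimum gave 2736 and 1742 at high and 3119 and 3049 at low density. Genes higher on both days numbered 182 at adjusted p below 0.01 and 43 with the fold minimum, and those lower on both 211 and 184. The other counts moved by less than 1.5 times, and no gene called under both settings changed direction. Same-numbered replicates share only a number: their deviations correlated at -0.55 to 0.229, with the own number the best match in 3 of 12 pairs. With the replicate block, day 6 had 833 and 606 genes, day 15 4274 and 4344, the difference 2109 and 3227, and the times 5732 and 5376, and 5968 and 6272. The block ended the calls of glycolysis at day 6 (0.0544) and of oxidative phosphorylation from day 6 to day 15 at low density (0.066), and of 11, 3 and 7 named genes at day 6, at day 15 and for the difference, and no other list call. The block also brought TFRC past the threshold at day 6 (adjusted p = 0.0403). An estimated correlation ended 17, 10, 15, 23 and 18 list calls at day 6, at day 15, for the difference and for the times at high and low density in turn, and fry ended endothelial (0.0958) and basement membrane (0.222) at day 6 and oxidative phosphorylation for the difference (0.171), and brought 1, 10, 8, 7 and 7 more lists past the threshold.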

Other observations

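Of the tests in this part, those of globin makeup, of granule genes, their scaling and of the splits of libraries were chosen after the result was seen, and those of the third day 15 low density library before. The labels name no eosinophil step. Yet the eosinophil granule gene PRG2 had the highest CPM of the 15963 genes tested at day 15 high density (12700 ± 2759 CPM). It was among the highest at low density (18560 ± 5066 CPM, log2 0.55, adjusted p = 0.0368). CPM takes no account of transcript length. CLC (3016 ± 798 and 4109 ± 900 CPM; 0.45, 0.0384), EPX (2463 and 3389 CPM; 0.46, 0.113) and MPO (1706 and 2047 CPM; 0.26, 0.291) were also abundant. Neutrophil granule genes ranged from MPO, the most abundant of those examined, through PRTN3 (470.4 and 634.2 CPM), LYZ (157.9 and 242.8 CPM) and AZU1 (136.2 and 196.1 CPM) to CTSG (15.1 and 20.9 CPM) and ELANE (0.739 and 1.05 CPM). Of the eosinophil granule genes, RNASE3 was low (5.69 and 8.21 CPM). The receptors CCR3 (1.38, 0.00345; 2.61 CPM at low density), IL5RA (0.60, 0.0176) and SIGLEC8 (0.73, 0.0012; 16.2 to 27.0 CPM) were higher at low density. With library totals alone, CCR3 (1.14, 0.0104) and SIGLEC8 (0.50, 0.012) kept their call, whereas PRG2 (0.31, 0.178), CLC (0.21, 0.258) and IL5RA (0.36, 0.117) did not. The mast cell, basophil and eosinophil list took 1.90 ± 0.431% of counts at high and 2.31 ± 0.490% at low density.

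Globin makeup was compared as shares. HBE1 made up 54.5 ± 2.4% of beta-like globin counts at day 15 high density and 60.2 ± 2.66% at low density, and HBG1 with HBG2 45.3 ± 2.4% and 39.7 ± 2.65% (exact permutation p = 0.1 for each, the smallest possible with 3 against 3). HBZ made up 46.7% and 49.2% of alpha-like counts (exact permutation p = 0.2). HBB made up 0.00552% and 0.0119% of beta-like counts (exact permutation p = 0.1). In these shares of HBE1, of HBG1 with HBG2 and of HBB, all 3 libraries of one density lay above all 3 of the other.

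Day 15 low density replicate 3 lay between the densities. On a line from the other low density libraries (0) to the high density libraries (1) it was at 0.332, and at 0.333 with the globins left out. Globins took 6.74% of its counts, against 8.52% and 8.79% in replicates 1 and 2. Leaving them out could thus move the position only slightly, and no conclusion on globin-led scaling is drawn from it. Replicates 1 and 2, each set against the remaining low density libraries, replicate 3 included, were at -0.188 and -0.0709. Their positions kept the main scaling and only dropped the globin rows, so they are not on the same line. In genes at least 4-fold different without it, its share of the way to the high density mean was 0.187 over 138 higher genes (quartiles 0.0486 to 0.316) and 0.153 over 863 lower genes (0.0829 to 0.258), a difference of 0.0337. An admixture of high density material would shift both sets by an equal share, but the test compared only their medians. Single erythroid genes did not share 1 shift. SLC4A1 was at 1519 CPM in replicate 3 (1523 and 1279 in replicates 1 and 2) and GYPA at 271.7 (253.1 and 221.8). HBZ was at 14490 CPM (21990 and 24150), part of the way to the high density libraries. The test therefore cannot single out admixture. Admixture and a culture at an intermediate stage both stay open, and no biological explanation was tested.

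For comparisons of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. At day 6 the real split, the only 1 of 10 with as many, gave 1696 genes (highest other 1), at day 15 8742 (3), from day 6 to day 15 11213 at high density (0) and 12304 at low density (0). Each other split mixes the densities or the days within its groups, which widens the spread within groups. Few calls there follow largely from that mixing, so no support is drawn from these numbers.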
